A study of Mus musculus with 8 samples.

How the data were processed

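Gene expression was measured in 6 bulk libraries of whole kidney (3 control and 3 FAN) and in 2 single-cell FAN samples. Per the labels, all mice were adult C57BL/6. The submitters' processing notes name Cell Ranger and STAR, without versions or settings, and the builds mm10 and GRCm38.p4. The kit text of the labels names a 10x 3' kit for all 8 samples, so the bulk library method is uncertain.

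The bulk values are normalised read signal: as deposited, every value was a whole multiple of a step particular to its library (steps 0.853 to 1.11, 100% of values within a relative tolerance of 1e-06), which is the form of reads divided by a scaling factor, and the header states no unit. The design had assumed counts or CPM-like values, so the test planned for normalised values was used. No count test was run. Row names with the endings that HTSeq writes held 3 non-gene rows, which made up 44.8% to 51.6% of each library's sum, of which reads without a unique alignment were 39.6% to 45.9% of the sum. These rows were left out of all tests. The table listed 24689 genes, of which 99.5% of identifiers matched GENCODE M21. The most abundant gene of a library (Kap, Gpx3 or Spp1) took 2.04% to 3.90% of its gene sum. Between replicate pairs the median squared difference was 4.01 to 22.1 times what read sampling gives.

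The single-cell values are, as deposited, the natural log of 1 plus UMIs per 10,000, rounded to 2 decimals, with a cluster number for each cell. Per the values, cells held 201 to 2862 genes, and no mitochondrially encoded gene was listed, so no mitochondrial filter could be applied. UMIs were recovered from the step of each cell and tested on simulated data, where 100% of 300 cells had a total within 2% of the truth.

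Bulk genes were tested with limma 3.58.1 in R 4.3.3 on log2 of the value plus 1, with a trend of variance on expression, for 21608 genes with a value of at least 1 in at least 3 libraries. Benjamini-Hochberg adjusted p under 0.05 was called, with no fold minimum and no covariate. On simulated data with 3 libraries per group, 91% and 87% of 2-fold changes and 99% of 4-fold changes were recovered, with 0% and 0.535% false calls, at the control spread and at the nephropathy spread. Within a group every simulated gene had the same dispersion, 0.00717 or, for the changed group at the nephropathy spread, 0.012. Changes were simulated only in genes with a control mean well over the minimum value of the real test. Recovery may thus differ for genes of lower level, and recovery and false calls may differ for genes of larger spread. Gene lists (18 pathway lists and 19 cell type marker lists with at least 5 tested members) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The lists overlap: 9 proximal tubule markers are in the transport list, all 14 injured proximal tubule markers are in the tubule injury list, and Spp1 and Il34 are in the cytokine and the tubule injury list.

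The comparisons, lists, markers, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names 12 anchor genes, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 and groups without overlap (predicted genes left out), and up to 3 members of each list in its main direction and 1 in the other. Bulk genes outside the rule are Rxra, Atp6v0c, its pseudogene, the MHC genes, Guca2b and those low in a group, and single-cell genes outside it are the nuclear receptors, Spp1 and the leading genes of a subcluster, all chosen after their values were seen. Some genes that the rule names are not reported here.

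Deposited clusters were named where at least 3 markers of a class exceeded 0.5 per 10,000 and 4 times the mean of the other clusters, and stayed unnamed where the share of markers found for the next class reached 0.75 of the best. Classes are called proximal tubule-like and so on, since names rest on markers. For each of 13 classes, up to 50 genes with a log2 of at least 1 over the next class and at least 50 CPM were tested as a set in bulk. The plan asked for these in each single-cell sample, but the table did not tie cells to samples, so pooled cells were used. Proximal tubule-like cells were reclustered with scanpy 1.11.5 and igraph 0.11.9 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.6), with metabolic, nuclear receptor, interferon, cytokine and cell death genes left out of the clustering genes. Correlations used cells thinned to 1000 UMIs, and those of beta-oxidation and the respiratory chain were set against 200 random lists of like expression. No background of free RNA was measured, and levels in T cell-like cells are given for comparison. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

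Alternatives were limma without the trend, quantile normalization, no filter, a pseudocount of 0.1, a test against a 2-fold change, the replicate number as a block, each library left out in turn, other clustering resolutions, set sizes of 25 and 100 genes, and no thinning. Equal gene sums per library, the estimated correlation for class sets, the comparison of proliferating cells and 5 further lists in the correlations were chosen after seeing the data. The test of injured-like against differentiated-like cells was not made, since the chosen resolution gave no injured-like class and the pooled table is 1 sample.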

Results

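Folic acid nephropathy (FAN) is a mouse model of kidney injury in which a high dose of folic acid damages the renal tubules. The series held 8 samples of adult kidney, labelled C57BL/6. Bulk RNA sequencing covered 3 control and 3 FAN samples of whole kidney, and droplet-based single-cell sequencing covered 2 FAN samples. FAN mice had received 250 mg/kg folic acid by intraperitoneal injection in 300 mM NaHCO3, and kidneys were collected on day 7. The labels of the control samples repeated this treatment text beside a disease label of control, so what the control mice received was not stated. Normalised read signal summed over genes was 29722465, 30029810 and 27190450 in control samples 1, 2 and 3. The corresponding sums in FAN samples 1, 2 and 3 were 21979051, 22185441 and 22187583. Replicate libraries of the same group differed by more than read sampling alone, and the limma p-values of genes below set changes against the spread between these samples. Camera p-values set the genes of a list against all other genes. At the preset correlation they treat genes as nearly independent. At this setting camera called 15 to 25 of 37 lists when the 6 libraries were split into groups that mix FAN and control. Such splits still held unequal numbers of FAN libraries on their sides, so these calls do not measure false calling.

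The bulk comparison asked how the kidney transcriptome differed 7 days after folic acid, with attention to the proximal tubule, its metabolism and the nuclear receptors named in the study title. Havcr1, which encodes kidney injury molecule 1, averaged 100.3 ± 14.5 in control and 14519 ± 13114 in FAN kidneys (normalised signal, mean ± SD, n = 3 each). Lcn2, which encodes the secreted injury marker lipocalin 2, averaged 96.6 ± 27.4 in control and 11603 ± 7927 in FAN kidneys. Slc34a1, the apical sodium-phosphate cotransporter of the proximal tubule, averaged 253360 ± 28281 in control and 61921 ± 30074 in FAN kidneys. The endocytic receptor gene Lrp2, which encodes megalin, averaged 65437 ± 2311 in control and 15966 ± 4623 in FAN kidneys. Ppara, a nuclear receptor that drives fatty acid oxidation genes, averaged 700.4 ± 48.0 in control and 222 ± 57.9 in FAN kidneys.

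The genes chosen as anchors before the data were examined passed the limma test on log2 values. Havcr1 rose by 6.70 ± 0.61 on the log2 scale (SE, n = 3 per group, adjusted p = 8.8e-05), and its FAN samples ranged from 3622 to 29073. Lcn2 rose by 6.72 ± 0.40 (adjusted p = 1.3e-05). Slc34a1 fell by 2.17 ± 0.43 (adjusted p = 0.00424) and Lrp2 fell by 2.08 ± 0.24 (adjusted p = 0.000307). Hnf4a, the nuclear receptor that maintains proximal tubule identity, fell by 1.23 ± 0.17 (adjusted p = 0.000717). Ppara fell by 1.69 ± 0.20 (adjusted p = 0.000327), and the estrogen-related receptor gene Esrra fell by 0.79 ± 0.15 (adjusted p = 0.00384). Ppargc1a, the coactivator of mitochondrial biogenesis, fell by 1.21 ± 0.20 (adjusted p = 0.00154). Cpt1a, which controls fatty acid entry into mitochondria, fell by 0.89 ± 0.15 (adjusted p = 0.00166), but its log2 change was -0.36 under quantile normalization, where the call ended (adjusted p = 0.0771, and from 0.00149 to 0.0771 over 12 alternatives). Under quantile normalization the log2 changes of Slc34a1, Hnf4a and Esrra were -1.44, -0.66 and -0.48, and the calls held. The matrix genes Col1a1 and Fn1 rose by 3.51 ± 0.24 and 2.91 ± 0.21 (adjusted p = 2.6e-05 and 2.7e-05).

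**Figure D1:**
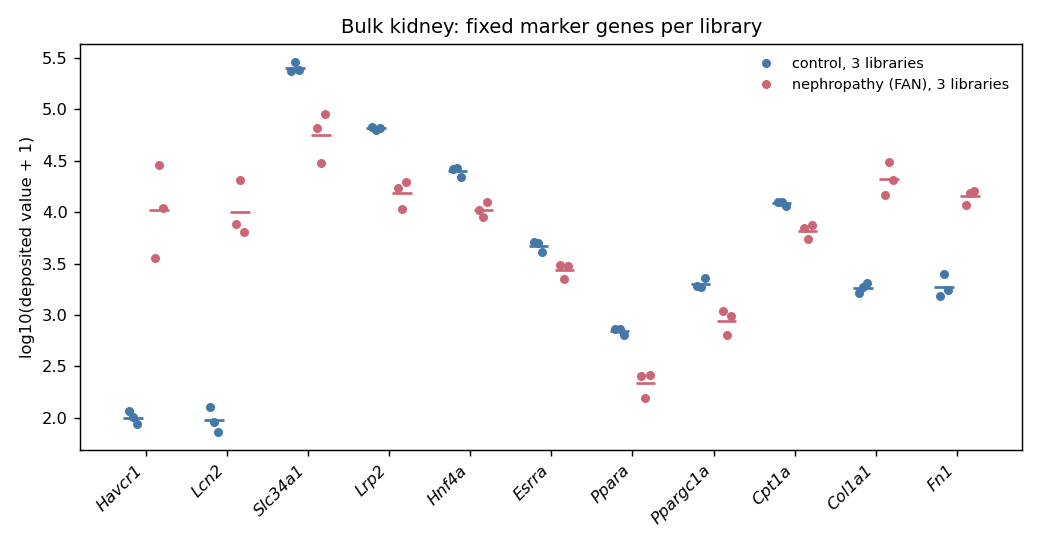
Each point is the log10 of the deposited value plus 1 of a marker gene in a bulk library (vertical axis), with control and FAN libraries side by side for each gene and a bar at the group mean (n = 3 each). Havcr1, Lcn2, Col1a1 and Fn1 sit higher in FAN, and the transport, nuclear receptor and fatty acid oxidation genes sit lower.

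On the GRCm38 build, with the GENCODE M21 annotation, the protein-coding gene Havcr1 (ENSMUSG00000040405.12) spans 46735080 to 46779578 on chromosome 11. Lcn2 (ENSMUSG00000026822.13) spans 32384633 to 32388252 on chromosome 2, and Slc34a1 (ENSMUSG00000021490.10) spans 55398187 to 55415592 on chromosome 13. Lrp2 (ENSMUSG00000027070.13) and Hnf4a (ENSMUSG00000017950.15) lie on chromosome 2, at 69424340 to 69586065 and at 163506808 to 163572910. Ppara (ENSMUSG00000022383.12) spans 85734983 to 85802819 on chromosome 15, and Esrra (ENSMUSG00000024955.12) spans 6910977 to 6921813 on chromosome 19.

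Across the kidney, 4467 of the 21608 genes tested were higher in FAN and 3974 were lower, at a limma adjusted p under 0.05. The groups did not overlap in 51.7% of genes, against 10% when 3 and 3 samples are grouped at random. Fitted changes reached 2-fold in 4630 of these 8441 genes, whereas 1153 higher and 187 lower genes passed a test against a 2-fold change. Under quantile normalization 3927 genes were higher and 4591 were lower, so the majority turned. Scaling every library to the same gene sum, an alternative chosen after seeing that these sums differed between groups, moved the split to 7904 higher and 1832 lower. That scaling shifted the median log2 change of all genes from 0.02 to 0.38. Relative to the shift, the median of the proximal tubule transport list was -1.67, that of mitochondrial beta-oxidation was -1.11, that of the respiratory chain was -0.45 and that of the nuclear receptors was -0.45.

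The largest rises by the rule for named genes were in Arhgap36 (log2 change 7.75 ± 0.39, adjusted p = 6.3e-06), Cxcl17 (7.25 ± 0.55), Adgra1 (7.15 ± 0.50) and Timp1 (6.93 ± 0.43), followed by Lcn2 and Havcr1. Cxcl17 encodes a mucosal chemokine, and Timp1 encodes an inhibitor of matrix metalloproteinases. The largest falls were in Ugt1a8 (-6.97 ± 0.46), Ugt1a9 (-5.98 ± 0.47), Serpina3b (-5.80 ± 1.53), Catspere1 (-5.54 ± 0.46), Ptprn2 (-5.29 ± 0.41) and Ugt1a10 (-5.06 ± 0.44). Ugt1a genes encode UDP-glucuronosyltransferases that share their 3' exons, so the division of reads among Ugt1a8, Ugt1a9 and Ugt1a10 is uncertain. Serpina3b averaged 45.3 ± 77.6 in FAN, and its call ended without the trend (adjusted p = 0.0603), without control sample 2 (adjusted p = 0.0502) and without control sample 3 (adjusted p = 0.0630), with a lowest adjusted p of 7.7e-06 over the alternatives.

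Proximal tubule transport genes fell as a group. Of 48 measured transporters and endocytic receptors, 42 fell, 1 rose and 5 did not pass the test, and 44 fell and 2 rose when adjusted over the list alone. Slco1a1, an organic anion transporter, fell from 7735 ± 3421 to 1167 ± 1052. Slc7a13, the aspartate and cystine transporter of the late proximal tubule, fell by 2.99 ± 0.75, and its call ended without the trend (adjusted p = 0.0529, and from 0.000378 to 0.0529 over the alternatives). Slc22a7, an organic anion transporter, fell by 3.14 ± 0.98 (adjusted p = 0.0329), a call that ended under 6 alternatives, with adjusted p from 0.00356 to 0.0990 over all 12. Without FAN sample 2 the log2 changes of Slc22a7 and Slc7a13 were -1.78 and -1.94. Abcc4, an efflux pump, rose by 0.82 ± 0.16. The list median was -1.68 (camera adjusted p = 1.6e-15, and adjusted p = 0.282 with an estimated correlation), or -1.13 relative to the median of all genes under quantile normalization. Among 17 proximal tubule markers, 15 fell and none rose, also when adjusted over the list alone, with a median of -1.96 (camera adjusted p = 2.4e-08, and adjusted p = 0.327 with an estimated correlation).

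Fatty acid oxidation genes fell in both organelles. In mitochondrial beta-oxidation, 25 of 29 genes fell and 4 did not pass, and 28 fell when adjusted over the list alone. Acadm, the medium-chain acyl-CoA dehydrogenase, fell by 2.27 ± 0.35, and Acsl1, which activates long-chain fatty acids, fell from 9302 ± 542 to 2379 ± 612. The list median was -1.12 (camera adjusted p = 5.0e-13, and adjusted p = 0.327 with an estimated correlation), or -0.75 relative to the median of all genes under quantile normalization. In the peroxisomal list, 36 of 40 genes fell and 1 rose, with the same counts when adjusted over the list alone. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, fell by 2.65 ± 0.32, and Abcd2, a peroxisomal fatty acid transporter, rose by 2.51 ± 0.44. The peroxisomal median was -0.91 (camera adjusted p = 3.1e-13, and adjusted p = 0.323 with an estimated correlation). Of 23 measured PPARA target genes, 15 fell and 2 rose, both over all genes and adjusted over the list alone. Cyp4a10, a fatty acid omega-hydroxylase, fell by 2.35 ± 0.20. The PPARA target median was -0.78 (camera adjusted p = 2.6e-05, and adjusted p = 0.269 with an estimated correlation).

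Other mitochondrial genes fell with a dependence on scaling. All 22 genes of the tricarboxylic acid cycle and pyruvate entry fell, also when adjusted over the list alone. They included Pcx, which encodes pyruvate carboxylase (-1.63 ± 0.25), and Mpc1, a subunit of the mitochondrial pyruvate carrier (-1.45 ± 0.14). The list median was -1.01 (camera adjusted p = 4.0e-11, and adjusted p = 0.327 with an estimated correlation), or -0.44 relative to the median of all genes under quantile normalization. In the respiratory chain and ATP synthase, 44 of 77 genes fell, 1 rose and 32 did not pass, and 48 fell and 1 rose when adjusted over the list alone. Sdha and Ndufs1, subunits of complexes II and I, fell by 1.48 ± 0.18 and 1.38 ± 0.19, and Sdha by 0.92 under quantile normalization. Ndufs5, another subunit of complex I, rose by 4.14 ± 1.09 from a mean of 5.53 in control, with an SD in FAN (227) as large as its mean (224). The call ended without the trend (adjusted p = 0.0574) and without control sample 1 (adjusted p = 0.0571), with a lowest adjusted p of 0.000255 over the alternatives. Ndufs5 read 465, 195 and 13.2 in FAN samples 1, 2 and 3, and its control mean was far below that of Ndufs1 (9589). Whether read mapping set the level of Ndufs5 was not tested. The respiratory chain median was -0.46 (camera adjusted p = 3.9e-11, and adjusted p = 0.364 with an estimated correlation), but relative to the median of all genes it flipped to 0.02 under quantile normalization (adjusted p = 0.348, the highest of 12 alternatives, with a lowest of 1.4e-15). Of 21 mitochondrial biogenesis factors, 13 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone. Opa1, which fuses inner membranes, fell from 3636 ± 202 to 1688 ± 221, a log2 change of -1.11, or of -0.73 under equal gene sums. Pprc1, a coactivator related to Ppargc1a, rose by 0.93 ± 0.13. The median of the biogenesis factors was -0.62 (camera adjusted p = 0.000391, and adjusted p = 0.233 with an estimated correlation).

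Gluconeogenic genes of the proximal tubule also fell, led by G6pc, the catalytic subunit of glucose-6-phosphatase, at -3.03 ± 0.38, and by Pck1, the cytosolic phosphoenolpyruvate carboxykinase, at -2.80 ± 0.47. Pck2, the mitochondrial form, rose by 0.92 ± 0.10. In all, 8 of 12 gluconeogenesis genes fell and 1 rose, and 9 fell when adjusted over the list alone. The median was -1.44 (camera adjusted p = 0.00162, and adjusted p = 0.327 with an estimated correlation), and the call ended under quantile normalization (median relative to all genes -0.71, adjusted p = 0.0622, and from 0.000220 to 0.0622 over the alternatives). The glycolysis list was not called (median 0.19, camera adjusted p = 0.133, and adjusted p = 0.327 with an estimated correlation), although 10 of its 22 genes rose and 4 fell, also when adjusted over the list alone. Hexokinase 2, encoded by Hk2, rose by 3.67 ± 0.32, and the glucose transporter gene Slc2a3 rose by 2.16 ± 0.29. Under quantile normalization the glycolysis list was called higher (median relative to all genes 0.54, adjusted p = 0.00403, and from 0.00403 to 0.213 over the alternatives). In folate and one-carbon metabolism, 11 of 24 genes fell and 5 rose, and 13 fell and 6 rose when adjusted over the list alone. Shmt2, mitochondrial serine hydroxymethyltransferase, fell from 7941 ± 813 to 2899 ± 891, and Mthfd1l, a mitochondrial formate-producing enzyme, rose by 2.33 ± 0.25. That list was not called (median -0.36, camera adjusted p = 0.0616, and adjusted p = 0.327 with an estimated correlation), but it was called lower without the filter (adjusted p = 0.0445), without control sample 1 (0.0470) and without FAN sample 2 (0.0407), with a highest adjusted p of 0.109, and its median relative to all genes was -0.18 under quantile normalization.

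Nuclear receptors moved in both directions. Of 46 measured receptors, 22 fell, 4 rose and 20 did not pass the test, and 22 fell and 5 rose when adjusted over the list alone. Besides Hnf4a, Ppara and Esrra, the largest falls were in Esr2 (-2.76 ± 0.48), Rxrg (-2.10 ± 0.38) and Hnf4g (-1.85 ± 0.22), of which Esr2 and Rxrg averaged 52.5 and 48.2 in control. The retinoid X receptor gene Rxra, chosen after its values were seen, fell by 0.98 ± 0.14. Nr4a1, an immediate early receptor, rose by 1.52 ± 0.24. The list median was -0.44 (camera adjusted p = 0.00167, and adjusted p = 0.364 with an estimated correlation).

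**Figure D2:**
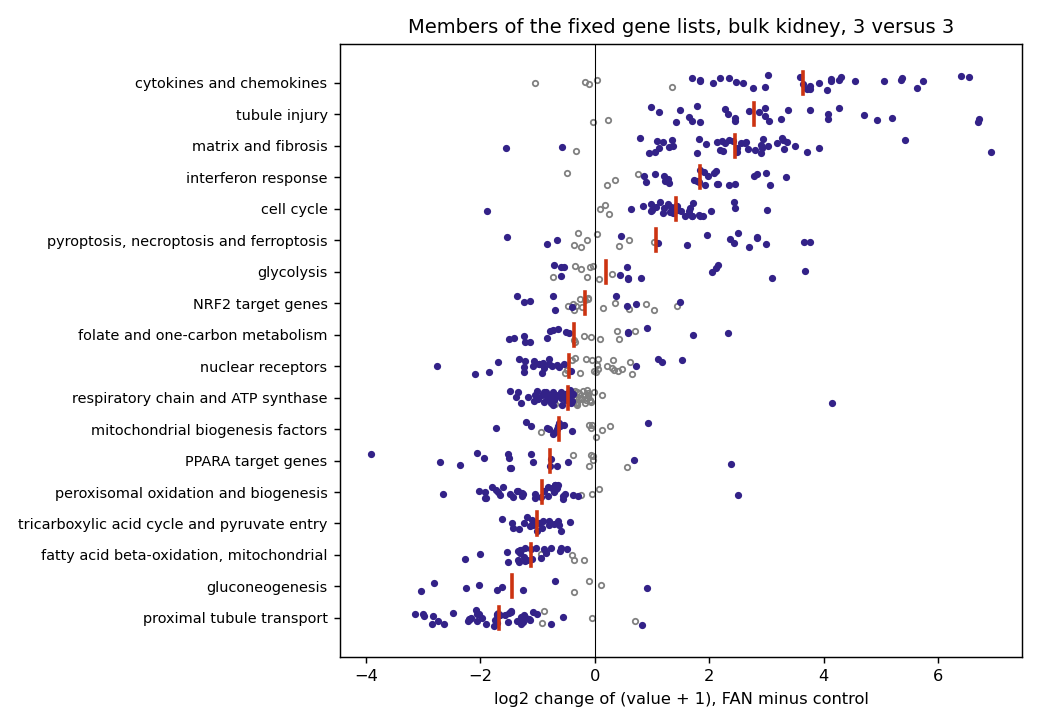
Each point is a gene of a list fixed before the data were examined, placed at its log2 change of value plus 1 between FAN and control (horizontal axis, 3 libraries each), filled where limma adjusted p was under 0.05, with a bar at the list median. Injury, matrix and cytokine genes lie to the right, transport and oxidation genes lie to the left, and the respiratory chain lies near -0.46.

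Injury, matrix and inflammatory genes rose. All 14 markers of injured proximal tubule rose, also when adjusted over the list alone, among them Cd44, a hyaluronan receptor, by 5.19 ± 0.19. Their median was 3.37 (camera adjusted p = 9.5e-11, and adjusted p = 0.233 with an estimated correlation). In the wider tubule injury list 28 of 30 genes rose and none fell, also when adjusted over the list alone, with a median of 2.78 (camera adjusted p = 1.6e-15, and adjusted p = 0.233 with an estimated correlation). Among 44 matrix and fibrosis genes, 41 rose and 2 fell, also when adjusted over the list alone. Mmp7, a matrix metalloproteinase, rose by 5.42 ± 0.43, the glycoprotein gene Tnc rose by 3.93 ± 0.19, and Timp3 fell by 1.55 ± 0.17, or by 1.02 under quantile normalization. The matrix median was 2.45 (camera adjusted p = 3.7e-19, and adjusted p = 0.233 with an estimated correlation). All 10 fibroblast markers rose, also when adjusted over the list alone, with a median of 2.49 (camera adjusted p = 4.8e-07, and adjusted p = 0.233 with an estimated correlation).

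Of 35 measured cytokines and chemokines, 30 rose and none fell, and 31 rose when adjusted over the list alone. Cxcl1, a neutrophil attractant, rose by 6.54 ± 0.27, and Ccl2, a monocyte attractant, rose by 6.40 ± 0.30. The list median was 3.64 (camera adjusted p = 1.7e-14, and adjusted p = 0.233 with an estimated correlation). Interferon response genes rose in 25 of 29 cases, also when adjusted over the list alone, with Mx1 at 3.07 ± 0.51 and a median of 1.84 (camera adjusted p = 4.6e-10, and adjusted p = 0.327 with an estimated correlation). Cell cycle genes rose in 32 of 36 cases and 1 fell, also when adjusted over the list alone. Mcm6, a subunit of the replicative helicase, rose from 147 ± 22.3 to 1182 ± 44.3, while Ccnd1, which encodes cyclin D1, fell by 1.88 ± 0.11. Their median was 1.42 (camera adjusted p = 1.5e-11, and adjusted p = 0.327 with an estimated correlation). Of 8 proliferation markers 6 rose, also when adjusted over the list alone, with a median of 1.44 (camera adjusted p = 0.000673, and adjusted p = 0.327 with an estimated correlation).

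In the list of pyroptosis, necroptosis and ferroptosis genes, 13 of 24 rose and 3 fell, and 14 rose and 3 fell when adjusted over the list alone. Casp4, an inflammatory caspase, rose by 3.66 ± 0.21, and Tfrc, the transferrin receptor, fell by 1.53 ± 0.15. The median was 1.06 (camera adjusted p = 0.00294, and adjusted p = 0.327 with an estimated correlation). NRF2 target genes showed 4 rises and 6 falls among 25, also when adjusted over the list alone, and the list was not called (median -0.16, or 0.38 relative to all genes under quantile normalization, camera adjusted p = 0.292, and adjusted p = 0.695 with an estimated correlation). Without control sample 1 the NRF2 median relative to all genes was -0.07, and without control sample 3 it was -0.28.

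Markers of other cell types moved with these groups. All 13 macrophage and monocyte markers rose, also when adjusted over the list alone, led by the lysozyme gene Lyz2 (4.88 ± 0.20), with a median of 3.86 (camera adjusted p = 4.8e-12, and adjusted p = 0.233 with an estimated correlation). T cell markers rose in 8 of 10 cases (median 2.61, camera adjusted p = 0.000967, and adjusted p = 0.327 with an estimated correlation), and B cell markers rose in 6 of 8 (median 2.03, camera adjusted p = 0.000604, and adjusted p = 0.233 with an estimated correlation). Dendritic cell markers rose in 6 of 8 cases (median 2.41, camera adjusted p = 0.00212, and adjusted p = 0.327 with an estimated correlation). Neutrophil markers rose in 6 of 7 cases (median 2.64, camera adjusted p = 0.00117, and adjusted p = 0.282 with an estimated correlation). NK cell markers rose in 3 of 8 cases (median 0.94, camera adjusted p = 0.0314, and adjusted p = 0.379 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.0590), under equal gene sums (0.136), without control sample 3 (0.0600), without FAN sample 1 (0.0662) and without FAN sample 3 (0.0809), and its lowest adjusted p was 0.00844, without FAN sample 2, where the median relative to all genes was 1.51. Adjusted over the list alone, 8 T cell, 6 B cell, 7 dendritic cell, 7 neutrophil and 3 NK cell markers rose.

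Markers of other nephron segments moved in both directions, and some of their lists were not called. Egf, the growth factor precursor made in the thick ascending limb, fell by 3.55 ± 0.80, but the 7 markers of that segment were not called (3 fell, median -0.61, camera adjusted p = 0.107, and adjusted p = 0.563 with an estimated correlation). Without FAN sample 1 that list was called lower (adjusted p = 0.0180, and from 0.0180 to 0.624 over the alternatives). Its median relative to all genes was -0.90 there, -0.26 without FAN sample 2 and -0.08 under quantile normalization. Of 7 distal convoluted tubule markers 3 fell, among them Pvalb at -2.69 ± 0.62 (median -0.76, camera adjusted p = 0.0277, and adjusted p = 0.462 with an estimated correlation). That call ended under quantile normalization (median relative to all genes -0.28, adjusted p = 0.230) and without control sample 3 (0.0596), and its lowest adjusted p was 0.00123. Without FAN sample 2 the median relative to all genes was -0.43. Thin limb markers rose in 5 of 8 cases and 1 fell (median 0.80, camera adjusted p = 0.0307, and adjusted p = 0.327 with an estimated correlation), a call that ended without the trend (adjusted p = 0.0618), under equal gene sums (0.109) and without control sample 2 (0.129), with a lowest adjusted p of 0.0102. The podocyte gene Nphs1, which encodes nephrin, fell by 1.77 ± 0.19. In all, 5 of 8 podocyte markers fell and 1 rose (median -0.84, camera adjusted p = 0.0204, and adjusted p = 0.379 with an estimated correlation), and the call ended under quantile normalization (adjusted p = 0.0595, and from 0.00364 to 0.0595 over the alternatives). Aqp2, the vasopressin-regulated water channel of principal cells, rose by 0.92 ± 0.22, or by 1.45 under quantile normalization, but its list of 8 markers was not called (3 rose, median 0.35, camera adjusted p = 0.107, and adjusted p = 0.563 with an estimated correlation). It was called higher under quantile normalization (median relative to all genes 0.79, adjusted p = 0.0120) and without FAN sample 2 (0.48 and 0.0127), and its highest adjusted p was 0.237. Adjusted over the list alone, 1 thick ascending limb marker rose and 3 fell, 4 distal convoluted tubule markers fell, 6 thin limb markers rose and 1 fell, 5 podocyte markers fell and 1 rose, and 3 principal cell markers rose.

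The remaining marker lists were not called. Intercalated cell markers had a median of -0.17 with 1 of 8 lower (camera adjusted p = 0.403, and adjusted p = 0.770 with an estimated correlation). Endothelial markers had a median of -0.10, or 0.14 relative to all genes under quantile normalization and 0.09 without FAN sample 2, with 2 of 10 higher and 1 lower (camera adjusted p = 0.950, and adjusted p = 0.981 with an estimated correlation). Pericyte and smooth muscle markers had a median of 0.31 with 3 of 8 higher, among them the growth factor receptor gene Pdgfrb from 1056 ± 85.9 to 4284 ± 801, and 1 lower (camera adjusted p = 0.276, and adjusted p = 0.379 with an estimated correlation). None of 6 erythrocyte markers passed (median -1.14, camera adjusted p = 0.411, and adjusted p = 0.751 with an estimated correlation). Relative to all genes, the intercalated cell median was -0.33 without FAN sample 1, -0.01 without FAN sample 2 and -0.11 under quantile normalization. The endothelial median was -0.05 without control sample 2 and -0.29 without FAN sample 3, and the pericyte median was 0.19 without control sample 2 and 0.63 under quantile normalization. The erythrocyte median was -2.17 without FAN sample 1, 0.29 without FAN sample 2, -1.76 without FAN sample 3 and -1.79 with a pseudocount of 0.1. Adjusted over the list alone, 4 pericyte and smooth muscle markers rose and 2 fell, and the counts of the other lists were the same. Over the 37 lists tested, camera called 16 higher and 12 lower with its preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.233 and 7 lists had an unadjusted p under 0.05. The rotation test fry called 30 of the lists. These included glycolysis (fry adjusted p = 0.000186), pericyte and smooth muscle (0.00811) and folate (0.0199), which camera did not call. Distal convoluted tubule markers, called by camera, were not called by fry (fry adjusted p = 0.141).

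The next comparison asked which cell classes the genes that changed in bulk belonged to, using genes enriched in each class of the single-cell table. Genes enriched in proximal tubule-like cells fell, with 39 of 49 lower, 1 higher and a median log2 change of -1.56 (camera adjusted p = 1.2e-12, and adjusted p = 0.368 with an estimated correlation). Genes enriched in macrophage and monocyte-like cells rose, with 46 of 49 higher and a median of 3.59 (camera adjusted p = 5.4e-24, and adjusted p = 0.168 with an estimated correlation). Sets of T cell-like (median 2.07), dendritic cell-like (1.83), NK cell-like (1.37), thin limb-like (1.06), B cell-like (0.97) and principal cell-like genes (0.36) were also called higher, at camera adjusted p of 7.6e-06, 1.2e-11, 7.6e-06, 0.00560, 0.0226 and 0.0201. With an estimated correlation their adjusted p was 0.416, 0.168, 0.168, 0.463, 0.168 and 0.530. Sets of podocyte-like (-0.55), distal convoluted tubule-like (-0.32) and intercalated cell-like genes (-0.32) were called lower, at camera adjusted p of 0.00995, 0.0103 and 0.00923, each with adjusted p = 0.530 with an estimated correlation. Endothelial-like (-0.16) and thick ascending limb-like (-0.44) sets were not called (camera adjusted p = 0.487 and 0.379, and adjusted p = 0.870 for each with an estimated correlation). Relative to all genes, the thick ascending limb-like median was -0.69 without FAN sample 1, -0.12 without FAN sample 2 and -0.27 under quantile normalization. The endothelial-like median was near 0 without FAN sample 2, -0.11 without control sample 2, -0.32 without FAN sample 3 and -0.38 under quantile normalization. The call ended for the distal convoluted tubule-like set under quantile normalization and without FAN sample 2 (adjusted p = 0.0548 and 0.0715), for the intercalated cell-like set without FAN sample 2 (0.0530) and for the principal cell-like set without FAN sample 1 (0.0949), with lowest adjusted p of 0.000855, 0.000580 and 0.00128. Under equal gene sums it ended for the B cell-like set (0.204) and the thin limb-like set (0.0697), with lowest adjusted p of 0.0126 and 0.000244. Relative to all genes, the thin limb-like median was 0.60 under quantile normalization, 0.61 without control sample 2 and 0.64 without FAN sample 1, and the principal cell-like median was 0.21 without FAN sample 1. The podocyte-like median was -0.86 under quantile normalization, the distal convoluted tubule-like median was -0.18 there and -0.22 without FAN sample 2, and the intercalated cell-like median was -0.18 without FAN sample 2. Of the 13 sets, 0 were called with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 8. The podocyte-like, distal convoluted tubule-like and intercalated cell-like sets were not called by fry (fry adjusted p = 0.140 for each).

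**Figure D3:**
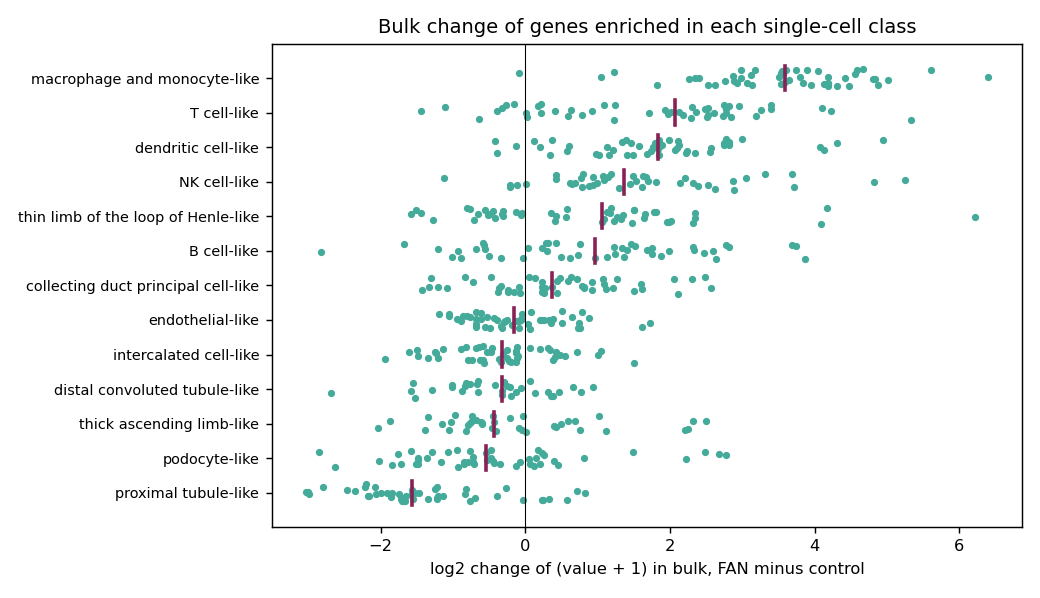
Each point is a gene enriched in a single-cell class, placed at its log2 change of value plus 1 in bulk between FAN and control (horizontal axis, 3 libraries each), with a bar at the median of the class. Macrophage and monocyte-like genes center on 3.59 and proximal tubule-like genes on -1.56.

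The single-cell table held 65091 cells and 15163 genes in 30 deposited clusters, with a median of 1462 recovered unique molecular identifiers (UMIs) per cell. Barcodes carried 8 suffixes, and neither the labels nor the table tied a suffix to either of the 2 FAN samples, so the table was treated as 1 pooled sample without tests, and values are given as ranges over suffixes. The labels call both single-cell samples FAN, but whether every suffix came from a FAN kidney is uncertain. Doublets were not called. Of the 30 clusters, 26 could be named from fixed markers. Proximal tubule-like cells formed a cluster of 44603 cells, or 68.5% of the total (41.5% to 78.0% by suffix). A separate cluster of 556 cells combined proximal tubule and proliferation markers.

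Metabolic gene lists differed among the cell classes, with levels given as UMIs per 10,000. Peroxisomal genes summed to 81.6 in proximal tubule-like cells (median over suffixes, range 73.5 to 99.9) and to 32.5 in thick ascending limb-like cells (27.8 to 33.8). Gluconeogenesis genes summed to 82.5 in proximal tubule-like cells (64.1 to 110.3) and to 11.5 in T cell-like cells (6.32 to 22.6). Mitochondrial beta-oxidation genes summed to 73.1 in proximal tubule-like cells (67.1 to 95.4), 60.4 in distal convoluted tubule-like cells (53.5 to 73.4) and 21.4 in T cell-like cells (19.6 to 31.1). Respiratory chain genes were lower in proximal tubule-like cells, at 1046 (851 to 1174), than in distal convoluted tubule-like cells, at 1666 (1166 to 1764), with overlap between the ranges.

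Among nuclear receptors, 44 were listed and 27 reached 0.5 per 10,000 in at least 1 class. Of these, 6 were highest in proximal tubule-like cells, among them Hnf4a, Nr1h4 and Rxra. Hnf4a stood at 4.19 per 10,000 (3.46 to 5.15 by suffix) against 0.510 in T cell-like cells. Nr1h4, the bile acid receptor FXR, stood at 1.23 (0.835 to 1.72) against 0.172 in T cell-like cells. Ppara stood at 0.446 (0.238 to 0.754), above the 0.0547 of T cell-like cells. Esrra was highest in intercalated cell-like cells, at 1.77, against 1.55 in proximal tubule-like cells, and Ppargc1a was highest in thick ascending limb-like cells, at 5.05, against 1.07 in proximal tubule-like cells. Havcr1, in contrast, stood at 0.0197 in proximal tubule-like cells and at 0.0249 in T cell-like cells. Of the 14 markers of injured proximal tubule, Spp1 alone exceeded 0.5 in proximal tubule-like cells, at 6.04 against 2.84 in T cell-like cells.

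The planned comparison of injured-like with differentiated-like proximal tubule cells asked how metabolism differs between these states, but no injured-like class was found at the chosen clustering resolution of 0.6. None of the 14 subclusters of 45159 proximal tubule-like cells there carried 3 or more injured markers. At a resolution of 1.0, 1 of 19 subclusters did, with 57 cells and 7 markers (Vcam1, Sox4, Cryab, Spp1, Clu, Krt8 and Krt18). Transport genes summed to 74.7 per 10,000 in it and to 185 in the other proximal tubule-like cells, a ratio of 0.403, and these genes had taken part in the clustering. Among lists kept out of the clustering, mitochondrial beta-oxidation had a ratio of 0.672, peroxisomal genes 0.564, the respiratory chain 1.03 and nuclear receptors 0.818. No suffix held 20 of the 57 cells, so these values carry no spread. Its leading genes included Ubd, Stc2, Cp and Akap12, which belong to the thin limb-like set, and Wt1, a podocyte marker. Of 8 podocyte markers, 1 was found. Slc34a1 stood at 15.1 in it, against 42.6 in proximal tubule-like cells and 5.81 in B cell-like cells, the next highest class. Havcr1 stood at 0.283 in it, against 0.0197 in proximal tubule-like cells and 0.492 in dendritic cell-like cells, its highest class. Whether these were proximal tubule cells is uncertain. The search covered only the proximal tubule-like and the proliferating proximal tubule-like clusters. Several injured markers were highest in thin limb-like cells, among them Cryab at 67.4 and Spp1 at 60.9, but Havcr1 and Lcn2 were not. Transport genes summed to 99.2 in thin limb-like cells. However, Slc34a1 and Lrp2 were no higher there than the 5.81 and 1.62 of B cell-like cells. The sum thus came mainly from other members of the list, and which members made it up was not examined. Whether the thin limb-like cluster held injured proximal tubule cells was not tested.

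Proliferating proximal tubule-like cells were compared with the other proximal tubule-like cells within each suffix, a comparison chosen after seeing the data. In the 4 suffixes with at least 20 cells of each kind (536 proliferating cells), transport genes were lower in proliferating cells in 4 of 4, at 86.7 against 173 per 10,000 (medians over suffixes, ratios from 0.467 to 0.584). Slc34a1 had a ratio of 0.507 (0.388 to 0.557). Peroxisomal genes were lower in 4 of 4 suffixes at 0.660 (0.597 to 0.727), and mitochondrial beta-oxidation genes were lower in 4 of 4 at 0.810 (0.730 to 0.833). Gluconeogenesis genes were lower in 4 of 4 at 0.706 (0.621 to 0.769). Respiratory chain genes had a ratio of 0.994 (lower in 3 suffixes and higher in 1), tricarboxylic acid cycle genes 1.08 (0.968 to 1.16) and nuclear receptors 0.881 (0.863 to 1.03), without a common direction. The tubule injury sum was higher in 4 of 4 suffixes at 2.91 (1.27 to 4.50). Pooled over suffixes, Spp1 made up 14.7 of 25.5 per 10,000 in proliferating cells and 6.04 of 10.8 in proximal tubule-like cells. Spp1 was thus a large part of both sums, and the rest of the sum was also higher in proliferating cells. Havcr1 had a median of 0 in proliferating cells against 0.0161 in the others, lower in 2 suffixes and higher in none. Lcn2 had medians of 0 and 0.0213, lower in 3 of 4 suffixes and higher in 1. These levels were so near 0 that zero counts set the directions, so no direction can be read for either gene.

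**Figure D4:**
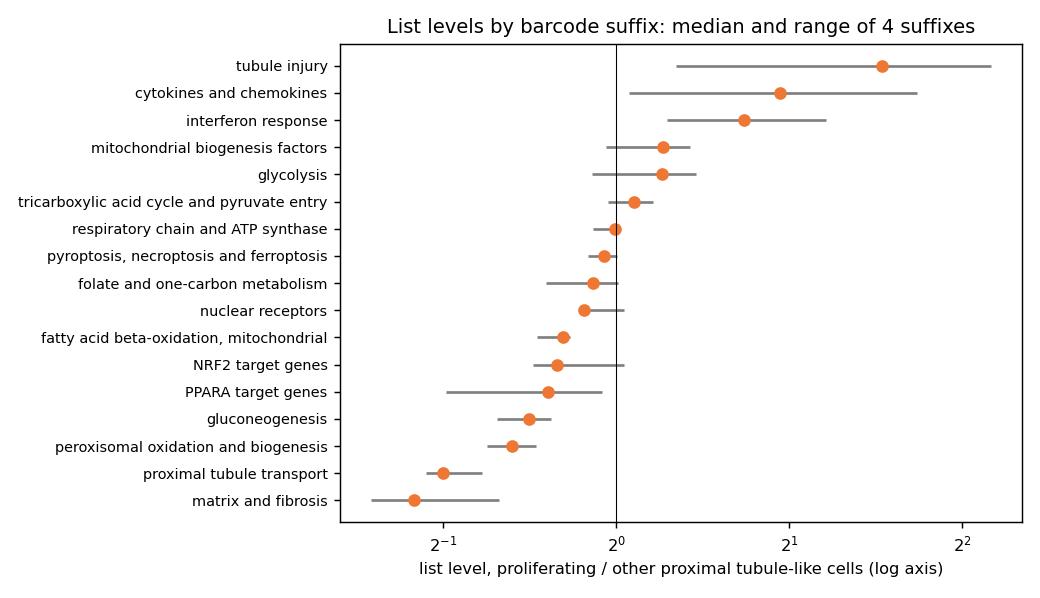
Each point is the median over 4 barcode suffixes of a gene list's level in proliferating proximal tubule-like cells divided by its level in other proximal tubule-like cells (horizontal axis, logarithmic), and the line is the range over suffixes. Transport, peroxisomal and mitochondrial beta-oxidation lists lie below 1, tubule injury lies above 1 and the respiratory chain lies at 0.994.

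The last planned comparison asked whether metabolic genes varied with differentiation across single proximal tubule-like cells. After each cell was thinned to 1000 UMIs, which left 34714 of 44603 cells and removed 9889 shallower ones, the share of transport genes was correlated with the share of each metabolic list within each suffix. Mitochondrial beta-oxidation gave a median Spearman correlation of 0.133 (-0.059 to 0.388 over 8 suffixes), above 0 in 5 of 8 suffixes, and 0.118 without thinning. Nuclear receptors gave 0.130 (-0.025 to 0.180), above 0 in 7 of 8, and 0.139 without thinning. Respiratory chain genes gave -0.676 (-0.814 to -0.506), below 0 in 8 of 8, and -0.700 without thinning. Among 5 lists added after seeing the data, the median was -0.211 for the tricarboxylic acid cycle (unthinned -0.274), -0.299 for glycolysis (-0.371), -0.013 for peroxisomal genes (-0.043), -0.065 for gluconeogenesis (-0.057) and 0.133 for tubule injury (0.104). Shares of a fixed total compete, and the respiratory chain took 108 of 1000 UMIs. Against random lists of like expression, its correlation lay at percentiles from 0 to 7 by suffix, outside their central 95% in 5 of 8 suffixes. Beta-oxidation lay inside the central 95% in 8 of 8 suffixes. Nuclear receptors and the 5 added lists were not set against random lists.

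**Figure D5:**
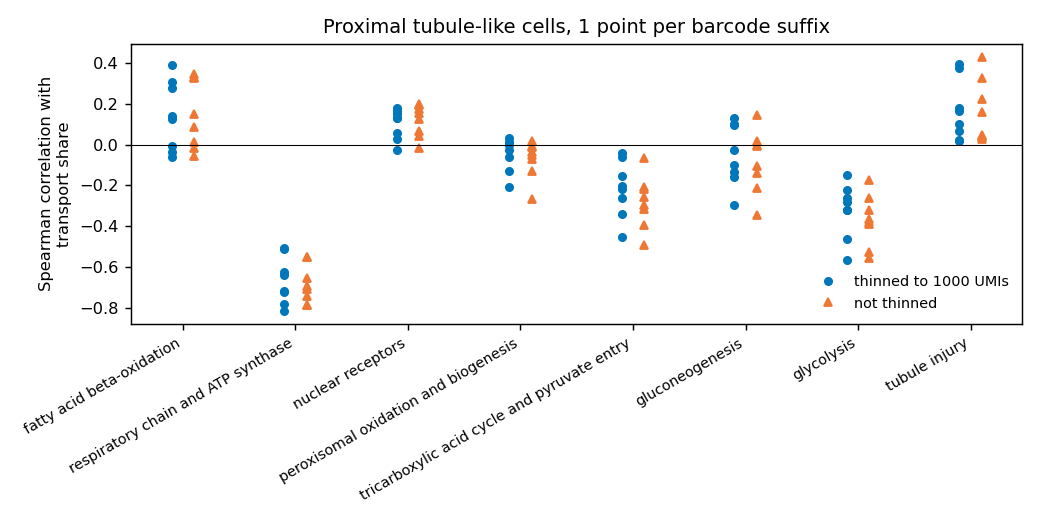
Each point is the Spearman correlation, across proximal tubule-like cells of a barcode suffix, between the share of transport genes and the share of another list (vertical axis, no unit), with cells thinned to 1000 UMIs or not thinned. Respiratory chain values lie between -0.814 and -0.506 after thinning, and beta-oxidation values lie on both sides of 0.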

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

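Equal gene sums and the estimated correlation for class sets were chosen after seeing the data, and the other alternatives were planned. Relative to the median of all genes, the respiratory chain list turned from -0.49 to 0.0185 under quantile normalization, and the cause was not tested. Of 8441 genes, 1340 passed a test against a 2-fold change, which is a stricter question by construction. Camera with an estimated correlation called 0 of 37 lists and 0 of 13 class sets, against 28 and 11 with the preset correlation, because the estimate enters the variance of each set. Without each library in turn, the called genes ranged from 6297 (without control sample 2) to 7730 (without FAN sample 2), the lists from 26 to 30 and the class sets from 9 to 11. In a limma fit with the replicate number as a block (replicate block), 8295 genes were called, of which 7888 were among the 8441, with 28 lists and 11 class sets. Deviations of same-numbered samples correlated at 0.0186, 0.0440 and 0.0346, each the highest for its samples but under 0.1. No label says that the numbers mark pairs, and correlations this small cannot decide it. Over the list comparisons under 12 alternatives, 424 stayed on their side of the threshold, 12 lost the call, 7 gained it and 1 reversed, and among the 424 the NRF2, endothelial and erythrocyte lists, which were not called, changed sign. For class sets 150 stayed on their side and 6 lost the call, and for 134 named genes 1547 comparisons stayed and 61 lost it, with no gene reversed. Not run were the alternatives of the comparison of injured-like cells, the 30% mitochondrial filter and the correlations within those states. Doublets were not called.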

Other observations

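The single-cell table and the bulk FAN libraries differed in injury and matrix genes, and whether every cell came from a FAN kidney is uncertain, which limits what the absence of an injured-like class and the other single-cell values say about FAN. Havcr1 took 1.65 to 13.1 per 10,000 of the gene sum in FAN bulk libraries and 0.0315 to 0.0385 in control libraries, and 0.0175 of UMIs in all single cells (0 to 0.0382 by suffix). Lcn2 took 2.88 to 9.34 in FAN bulk libraries, 0.0266 to 0.0425 in control libraries and 0.0803 in single cells (0.0125 to 0.166). Col1a1 took 6.62 to 13.8 in FAN bulk libraries, 0.549 to 0.747 in control libraries and 0.00299 in single cells. Shares of reads in whole tissue and shares of UMIs in single cells are unlike measures. No cluster was named fibroblast-like, and Col1a1 in single cells lay below even the control libraries, so its gap cannot tell FAN from control cells. Slc34a1 took 13.6 to 40.5 in FAN bulk libraries, 79.0 to 95.2 in control libraries and 30.5 in single cells (20.3 to 41.1).

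In bulk, 45 genes had at least 50 in every FAN library and at most 5% of the lowest FAN value in every control library, and 7 genes showed the opposite. The 7 genes were Ptprn2, Ugt1a8, Ugt1a9, Gm15374, Gm15375, Gm12901 and Gm15459. Catspere1, a pseudogene with a mean of 0.335 in FAN, missed the rule with a lowest control value of 44.8. H2-Ea, an MHC class II gene that is silent in C57BL/6 mice, read at most 5.55 in the control libraries and 5573, 76.3 and 1.02 in FAN samples 1, 2 and 3. The H2-Ea value of FAN sample 1 was thus at odds with its strain label, and the cause stays open. FAN sample 1 also stood apart from FAN samples 2 and 3 in the class I genes H2-Q7 (11.1, against 189 and 809.8) and H2-D1 (7032, against 21576 and 21515). Atp6v0c fell from between 694 and 842 in control to between 93.9 and 361 in FAN, while its pseudogene Atp6v0c-ps2 rose from between 5.97 and 7.04 to between 447 and 976.

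Of the tests below, the strain and pseudogene loss tests were chosen only after the result was seen, and the decision rules for strain, MHC and pseudogene loss and the interval of the spread were set after their values had been seen. The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. For genes the real split gave 8441 calls and the highest other split 0, so 1 of 10 splits gave as many. For lists the real split gave 28 calls and the highest other 25, so 1 of 10 gave as many. For class sets the real split gave 11 calls and the highest other also 11, so 2 of 10 gave as many. Camera with its preset correlation thus called 15 to 25 lists in splits that mix the groups. Each mixed split kept unequal numbers of FAN libraries on its sides, so part of the contrast remained in its list and class set calls. Mixing also put the group difference into the spread within sides, which works against gene calls. None of these counts therefore measures false calling.

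The first pattern was the lower transport genes in FAN kidneys. The prediction was that a lower share of proximal tubule cells alone would lower all genes enriched in these cells alike. Beyond sampling error their log2 changes had an SD of 0.900 (0.684 to 1.06), from -3.03 for G6pc to 0.83 for Guca2b, so they did not fall alike. Genes entered this set at a log2 of at least 1 over the next class, so reads from other cells could also make falls unequal. With sampling error included the SD was 0.963, against 0.657 in the endothelial-like set and 1.54 in the thin limb-like set. The spread therefore cannot decide whether a lower share was the whole cause. A bias of gene length and GC content was argued against, since the list median was -1.82 after the trend was removed and -1.68 before. A change of expression within proximal tubule cells, with or without some loss of these cells, may contribute, and bulk values cannot divide the parts.

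The second pattern was these genes with at most 5% of the other bulk group's lowest value. Of the 7 genes low in FAN, 4 were pseudogenes (odds ratio 186 against other expressed genes). While 4 of the 7 genes lie at the Ugt1a locus, 2 of the 3 outside it were pseudogenes (odds ratio 278, 14.4 to 14256). These pseudogenes had prompted the test, so neither odds ratio is support for a strain difference between the groups, which stays open. Genes low in control gave an odds ratio of 9.79. A non-b MHC haplotype shared by the FAN group was argued against, since H2-Ea exceeded 10% of H2-Aa in 1 FAN library (29.9%), against 0.388% and 0.00373% in the other FAN libraries, an outcome that the prediction had not named. A genetic difference of FAN sample 1 alone stays open. Loss of pseudogene reads in a single direction stays open, since 2 pseudogenes were low in control and 4 in FAN, which is too few to decide.

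The third pattern was the correlation of beta-oxidation and transport shares across proximal tubule-like cells. After thinning to an equal depth of the cell, 5 of 8 suffixes had a correlation over 0.1, and the median was 0.133 (-0.059 to 0.388, SD 0.169) against 0.118 without thinning. Thinning thus did not lower the median, but the correlation did not exceed 0.1 in every suffix or by more than its SD, so depth stays open. Co-variation shared by any genes of like expression is consistent with the values, since in 8 of 8 suffixes the correlation lay inside the central 95% of random lists (percentiles 51.5 to 94.5). The correlation therefore gives no evidence specific to beta-oxidation.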
